A study of Danio rerio with 2 samples.

How the data were processed

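RNA was measured by sequencing in 2 samples of zebrafish larvae at 5 days post-fertilization (dpf), each a pool of 20 whole larvae. One pool came from wild-type siblings and the other from clutch-mates homozygous for the lri12 mutation. Total RNA was extracted with a silica column kit, and libraries followed the sequencer maker's standard protocol, per the labels. The labels do not name the gene that lri12 affects, so the targeted gene could not be used to check the labels. One title spells the line with 2 letters exchanged, and its genotype field reads lri12.

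The data were 1 deposited table with a row for each of 40114 loci. Its columns carry the names of a Cuffdiff comparison of wild type with mutant, per the file headers. The deposited value of each pool was taken as FPKM, fragments scaled by transcript length and library size, which is what Cuffdiff writes in those columns. No label states the unit. The submitters' processing notes name CASAVA, Bowtie and the genome build Zv9, with no versions. Strand, annotation and multi-mapping rules are not given in the sources used here. The deposited p-values and q-values are the authors' own, made from 1 pool against 1 pool. They were quoted as the authors' and not used as a test of genotype. The deposited column of log2 ratios was not used to compare genes because a spreadsheet had turned part of its cells into text. In a check over 31084 loci with values in both pools, its largest difference from the log2 ratio of those values was 0.31.

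The table marks 31308 loci as tested, 8787 as too low to test and 19 as failed estimates. The failed ones were left out, among them the locus of the muscle actin actc1b. Of all loci, 8509 carry no gene symbol. They hold 13.1% of the summed FPKM in wild type and 17.0% in the mutant and were kept out of the gene comparison. These shares lean on single short loci: a locus of 100 bases on chromosome 5 stood at 10491 FPKM in wild type and 40365 in the mutant. In 735 loci several symbols are joined, and such a locus counted as 1 gene. In 17 loci the symbol has become a calendar date. Loci that share a symbol were summed, as 510 of the 27458 symbols required. Genes at overlapping loci, or with near-identical copies, may have had reads divided between them by the authors' program. Coordinates are those of Zv9, counted from 1, and span the whole locus. No genome of that build was used, so exons and untranslated regions are not described.

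Absolute depth is unknown. Among 1786 low loci with a value in both pools, the commonest log2 ratio of mutant to wild type was -0.15, held by 261 loci within 0.01. In all, 31.1% of these loci lay within 0.01 of that ratio or of the ratios that 2 or 3 reads against 1 would give. Those 5 windows cover 2.5% of the range from -2 to 2. Read as equal numbers of reads, the shift corresponds to 1.11 mutant reads for each wild-type read.

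Each gene was compared as log2((mutant FPKM + 1)/(wild-type FPKM + 1)), and every fold below is on this scale, which understates the difference of low genes. Genes with a mean of at least 1 FPKM over both pools entered. With 1 pool per genotype no test was run, and no p-value, standard error or count of significant genes was made. Genes at least 2-fold higher or lower were counted as a rule of size. For each of 59 gene lists (tissues, cell types, metabolic and stress pathways), the median log2 difference of its entering members was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean FPKM. A list was said to stand apart when it had at least 5 entering members and lay below the 1st or above the 99th percentile. This describes these libraries only. Members of a list are regulated together, so random lists understate the spread of such medians. By the limits alone, 1.16 of the 58 lists with enough members would stand apart by chance. Of 1844 list entries, 1304 matched a symbol as written, 222 matched through synonyms in gene name tables, one of them a RefSeq table of the assembly GRCz12tu used for names only, and 318 matched none.

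Named genes were the 15 highest and the 15 lowest with a mean of at least 5 FPKM and a symbol without a colon that does not start with LOC, CABZ, CU, BX, CR or ENSDARG, prefixes of clone or locus names, the 4 members furthest in the direction of each list that stood apart, up to 2 members of the other lists, and the 10 genes highest in wild type. A gene named for another reason is said to be chosen after its values were seen. Lists, rules and 6 alternatives (pseudocounts of 0.1 and 5, no filter, a mean of at least 5, rescaling to a median of 0, and the highest locus of each symbol) were fixed before the data were examined. An additional 2, only tested loci and no short non-coding RNA symbols, were chosen after seeing the data. In comparing settings, a count was taken as unchanged within 1.5 times, a list by its side of the percentile limits, a gene by its side of 2-fold, and the median of all genes within 0.1.

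The procedure was tested on simulated data: real wild-type levels with a made-up mutant column of random scatter, 200 genes changed and 1 list shifted. The changed genes had at least 5 FPKM in wild type. The scatter was independent between genes, equal at all levels and small against 2-fold. Over 18662 genes, 100 of 100 genes changed by 2 on the log2 scale and 99 of 99 changed by 1.5 passed the 2-fold rule, against 0 of 18462 genes outside the 200. The remaining 1 of the 200 was also in the shifted list and was not scored. The shifted list stood apart, as did 2 of 57 others. With such scatter the 2-fold counts followed from the settings. They check the calculation and give no error rate for the real libraries. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with figures by matplotlib 3.10.9.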

Results

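The transcriptome of lri12 homozygous zebrafish larvae was compared with that of their wild-type siblings at 5 dpf, when larvae have hatched and the digestive organs are formed. Each genotype was represented by 1 library from 20 pooled whole bodies, so every difference below is between 2 libraries and has no replicate check. The libraries resembled each other closely. The Pearson correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.990. In both libraries the most abundant transcripts included those of fast muscle and of the mitochondrial genome. The parvalbumins pvalb2 and pvalb1, calcium-binding proteins of fast muscle, stood at 18576 and 16539 FPKM in wild type and at 19477 and 17877 FPKM in the mutant. The mitochondrial transcript mt-co2 stood at 14492 and 15906 FPKM. Sequencing depth is unknown in absolute terms. The commonest ratio among low loci, if read as equal numbers of reads, corresponds to 1.11 mutant reads for each wild-type read.

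The question put by the design was which transcripts differ between mutant larvae and their siblings. Of 18664 genes that entered, 54 were at least 2-fold higher and 82 at least 2-fold lower in the mutant. The median log2 difference was 0.004, and 86.7% of genes differed by less than 1.2-fold. Enzymes of the exocrine pancreas made up 6 of the 15 lowest named genes, and short non-coding RNAs made up 10 of the 15 highest. These counts depend on how low values are treated. With a pseudocount of 5 they were 22 and 40, and with a pseudocount of 0.1 they were 72 and 134.

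Digestive enzymes of the exocrine pancreas were lower in the mutant as a group. Of 17 measured members of this list, 12 were at least 2-fold lower, 5 lay between and 0 were at least 2-fold higher. The median log2 difference was -1.12, below all 10000 matched random lists. The phospholipase pla2g1b (chromosome 8, 41676784 to 41692286) was 4.21-fold lower, at 19.8 FPKM in wild type and 3.95 in the mutant. Amylase, amy2a (chromosome 2, 15433338 to 15447555), was 3.46-fold lower, at 148 and 41.9 FPKM. The elastase ela2 (chromosome 8, 21914201 to 21919752) stood at 1288 and 439 FPKM, and its neighbour ela2l at 1291 and 477 FPKM. These elastases are related copies, and how reads were divided between them is not known. Carboxypeptidases cpa4 and cpa1 were 2.90-fold and 2.88-fold lower. The gene listed as SYCN (1 of 2), named for the zymogen granule protein syncollin, was 2.70-fold lower at 305 and 112 FPKM. The single member above 0 was the transcription factor ptf1a, at 1.76 and 1.93 FPKM, named here after its value was seen. Islet genes did not share the difference. The list of islet hormones and islet factors had a median of 0.08 (92.96th percentile). Its members furthest from 0 were somatostatin sst1.1, 1.42-fold lower, and glucagon gcga, 1.32-fold higher.

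**Figure D1:**
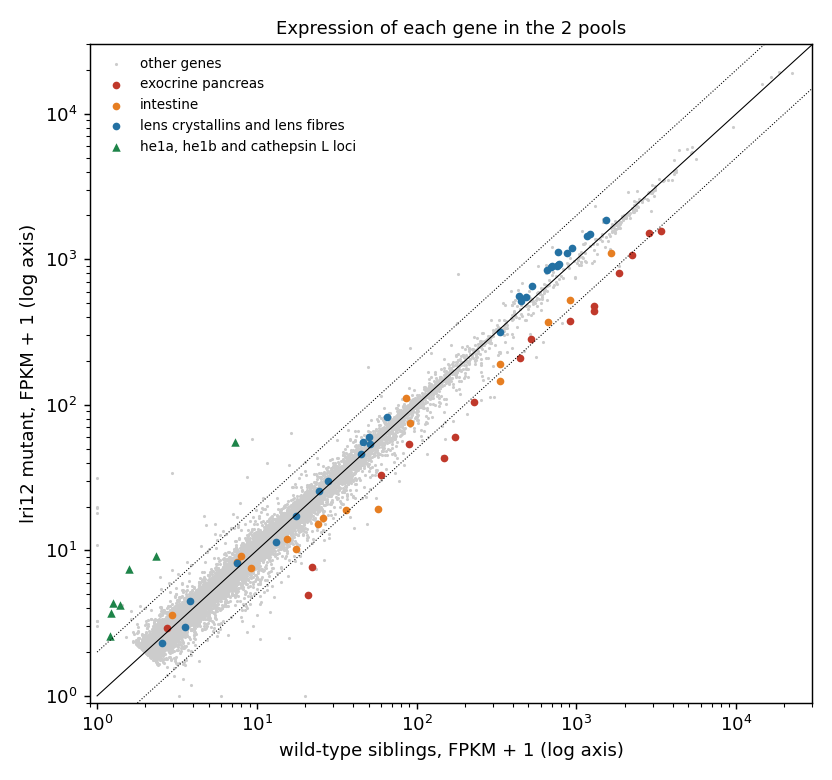
FPKM + 1 of each gene in the mutant pool (vertical, log axis) against the wild-type sibling pool (horizontal, log axis), 1 pool of 20 larvae per genotype. Each point is 1 gene, the solid line marks equal values and the dotted lines mark 2-fold differences. The exocrine pancreas points follow the lower dotted line, with 12 of 17 at or past it, lens points lie slightly above the solid line, and the he1a, he1b and cathepsin L loci, of which only ctsl1b has a mean under 1 FPKM, lie above the upper dotted line.

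Intestinal genes were lower too, by less. The list's median was -0.65 over 17 members, again below all random lists, with 2 members at least 2-fold lower and 15 between. The chitinase chia.3 (chromosome 11, 25040784 to 25043717) was 2.95-fold lower, at 56.0 and 18.3 FPKM. The bile acid binding protein fabp6 was 2.26-fold lower, the peptide transporter slc15a1b 1.91-fold and the fatty acid binding protein fabp2 1.78-fold. Of the 17 members, 4 stood above 0, and the highest was at 0.36.

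Liver and xenobiotic lists lay below the random lists, with a few members past 2-fold. In the hepatocyte list, 4 of 27 members were at least 2-fold lower, 1 was at least 2-fold higher and 22 lay between, with a median of -0.15 that exceeded 1 of 10000 random lists. The fetuin gene ahsg (7.65 and 1.75 FPKM), the liver fatty acid binding protein fabp10a (811 and 363 FPKM), the vitamin D binding protein gc (82.1 and 37.4 FPKM) and fetub (468 and 232 FPKM) were the 4 lower ones. The 10 members most abundant in wild type, examined after the list was seen, had a median of -0.21. Of these, 4 were at or below -0.5 and 3 at or above 0. Among them transferrin tfa stood at 537 and 424 FPKM, the apolipoprotein B gene apobl at 105 and 60.4 FPKM, the retinol carrier rbp4 at 1350 and 1269 FPKM and the apolipoprotein apoa1 at 1664 and 1755 FPKM. The higher member, also named after its value was seen, was a serpina1 locus listed at 0 in wild type and at 2.27 FPKM in the mutant. The more abundant locus that joins serpina1 and serpina1l was lower in the mutant, at 364 and 230 FPKM. Xenobiotic metabolism had a median of -0.22 over 24 members, below all random lists, and the 3 members at least 2-fold lower were the cytochromes P450 cyp2ad2 (48.2 and 14.1 FPKM), cyp3a65 (143 and 43.5 FPKM) and cyp2n13 (39.7 and 13.2 FPKM). The efflux pump abcb4 was 1.88-fold lower. In contrast, cyp2aa8, which is not a member of this list, was 2.49-fold higher, at 6.12 and 16.7 FPKM.

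Several other metabolic lists also lay lower. Cholesterol biosynthesis (-0.01, 28.47th percentile) and glycolysis (0.01, 55.33rd percentile) did not stand apart. Bile acid synthesis and transport had a median of -0.22 with 0 of 11 members past 2-fold. Its lowest members were the bile salt export pump abcb11b (1.65-fold) and the transporter slc10a2 (1.44-fold). Fatty acid and triglyceride synthesis had a median of -0.20 with 0 of 15 past 2-fold, led by elovl2, me1 and dgat2 at 1.65-fold, 1.64-fold and 1.58-fold lower. In fatty acid oxidation, with a median of -0.17, 1 of 19 members passed 2-fold, the uncoupling protein ucp1 at 253 and 106 FPKM. Complement and coagulation had a median of -0.20 with 0 of 14 past 2-fold and 3 above 0. Its highest member, si:dkey-8k3.2, named after its value was seen, was higher in the mutant at 2.42 and 4.86 FPKM, with a q of 0.043 in the authors' deposited table. Gluconeogenesis, at -0.12 (0.77th percentile), had 1 of 12 members past 2-fold, igfbp1b at 14.6 and 5.61 FPKM, in a locus shared with 15 other gene models. The key enzyme gene pck1 stood at 252 and 168 FPKM. This last list no longer stood apart without the filter on low values, where its median was -0.02.

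Photoreceptor genes were lower and lens genes higher. Cone photoreceptor genes had a median of -0.29 and rod genes one of -0.20, with 0 of 19 and 0 of 15 members past 2-fold. The calcium sensor guca1d was 1.71-fold lower, the cone phosphodiesterase subunit pde6h 1.61-fold, the blue cone opsin opn1sw2 1.33-fold and rhodopsin, rho, 1.26-fold. The locus of pde6h is shared with 6 other gene models. Genes of the pigment epithelium and visual cycle had a median of -0.21 over 14 members, with the retinol transporter gene stra6 1.26-fold lower. Lens crystallins and lens fibre genes had a median of 0.26, above all 10000 random lists, with 25 of 30 members above 0 and 0 past 2-fold. Among them crygm2d1 was 1.48-fold higher, at 763 and 1127 FPKM, and crygmxl2 1.29-fold higher. Crystallins are families of similar genes, and reads may have been divided among copies. Other retinal neurons had a median of 0.01.

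Several further lists stood below the 1st percentile of the random lists. Bone had a median of -0.39 over 13 members, below all of them, with 0 past 2-fold. Its lowest members were zgc:111821, matched to osteopontin spp1 as a synonym, and the vitamin D hydroxylase cyp24a1, at 1.91-fold and 1.87-fold. The list also holds hormone genes such as pth2, 1.44-fold lower at 2.22 and 1.24 FPKM. Its median is therefore not that of bone cell genes alone. Neuropeptides lay at -0.18 over 29 members, led by the melanin-concentrating hormone genes pmch and pmchl. The circadian clock list lay at -0.15 over 33 members, with zgc:77060, matched to nfil3-6, 1.96-fold lower and nr1d1 1.42-fold lower. Erythroid genes lay at -0.15 over 21 members, with the haemoglobin gene si:ch211-5k11.2 1.99-fold lower. Oxidative stress genes lay at -0.14 over 22 members, with abcc2 1.49-fold lower and superoxide dismutase sod1 1.22-fold lower. The macrophage list lay at -0.12 over 22 members, of which only ctsl.1 passed 2-fold, at 114 and 44.7 FPKM. Inner ear and lateral line genes lay at -0.12 over 21 members, with s100s 1.33-fold lower.

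The remaining lists that stood apart lay above the 99th percentile of the random lists. The inflammation and acute phase list had a median of 0.28 over 20 members, above all random lists, with 1 member at least 2-fold higher, 0 at least 2-fold lower, 19 between and 5 of the 20 below 0. The member past 2-fold was fosl1 (chromosome 14, 31609109 to 31617340), at 1.46 and 5.56 FPKM. The members next in size were also genes of AP-1 transcription factors: junbl was 1.83-fold higher, fos 1.77-fold and junb 1.75-fold. The integrated stress response list had a median of 0.11 (99.32nd percentile) with 0 of 19 members past 2-fold. Of these members 12 stood above 0 and 7 below, the lowest at -0.63. Its highest members were cebpb at 1.80-fold, the serine synthesis enzyme phgdh at 1.41-fold and atf3 at 1.39-fold. It no longer stood apart with a pseudocount of 5, where its median was 0.08. Proteasome subunits moved within a narrow band, with a median of 0.11 and 36 of 41 above 0, the highest being psmd8 at 1.18-fold. Extracellular matrix genes lay at 0.09 over 48 members, led by the metalloproteinase inhibitor timp2b at 1.88-fold. The cell cycle list lay at 0.08 (99.21st percentile) with 29 of 32 members above 0, led by the histone gene h2afx, at 26.3 and 34.5 FPKM, and cdc20, 1.25-fold higher.

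**Figure D2:**
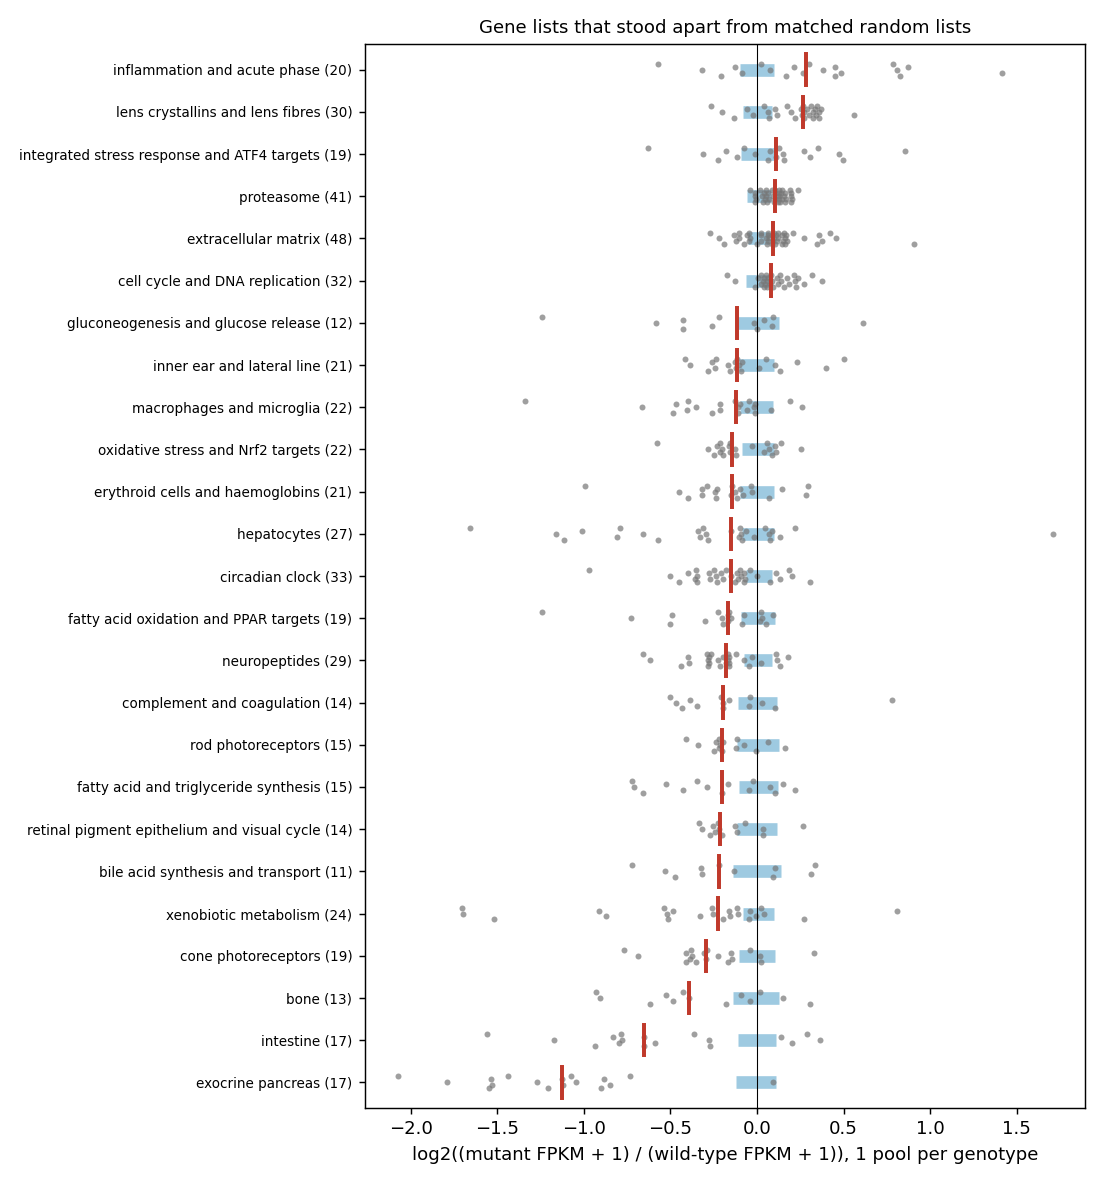
Log2 difference of mutant over wild type (horizontal, FPKM + 1) for the members of each of the 25 lists that stood apart, 1 pool per genotype. Grey points are genes, red bars are list medians, blue bands hold the central 99% of medians of matched random lists, and the number of entering members is in brackets. The exocrine pancreas median of -1.12 and the intestine median of -0.65 lie furthest from their bands, and 19 of the 25 medians lie within 1.2-fold of 0. Standing apart was judged by the 1st and 99th percentiles, which are narrower than the bands. The medians of cell cycle, integrated stress response and gluconeogenesis therefore lie inside their bands.

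Among single genes, the hatching enzyme gene he1a (chromosome 22, 14195689 to 14259479), which is expressed in the hatching gland, stood at 6.32 FPKM in wild type and 55.0 FPKM in the mutant, 7.64-fold higher. It shares its locus with 4 other gene models. The semaphorin gene sema7a (chromosome 25, 27710885 to 27737885) stood at 1.94 and 32.9 FPKM, 11.5-fold higher, with a q of 0.999 in the authors' deposited table. The symbol stk19, summed over 4 loci, was 3.70-fold higher, and its highest locus is shared with 9 other gene models. The ammonium transporter gene rhcgl1 was 3.15-fold lower, the nuclear receptor gene nr5a5 2.79-fold lower and AHSG, a second fetuin symbol on chromosome 2, 3.23-fold lower. Of 72 short RNA symbols that entered, 18 were at least 2-fold higher and 4 at least 2-fold lower. U8, dre-mir-363, dre-mir-10d and SNORA19 were listed at 0 in wild type and at 30.6, 18.9, 18.4 and 17.1 FPKM in the mutant, and SNORA65 was listed at 0 in the mutant and at 18.9 FPKM in wild type. In the authors' deposited table the smallest q of U8 was 0.339 and that of the others 0.999. The 5.8S ribosomal RNA symbol stood at 180 and 790 FPKM, and the signal recognition particle RNA at 48.3 and 180 FPKM summed over 74 loci. SNORA26 was 3.89-fold higher. SNORA57, SNORA16 and U4 were 3.48-fold, 3.12-fold and 2.69-fold higher as sums over loci, but by their highest locus SNORA57 was lower in the mutant, at -0.18 on the log2 scale, and the other two came under 2-fold. AL935186.6, a clone-based symbol that the naming rule did not exclude, beside the 5.8S locus on chromosome 4, was 2.67-fold higher. With a pseudocount of 5, the differences of ahsg, nr5a5, igfbp1b, fetub, cyp2aa8 and fosl1 came under 2-fold. With a pseudocount of 0.1, 5 named members of lists passed 2-fold on the lower side: the glucokinase gene gck (-1.36), hsp70 (-1.09), zgc:111821 of the bone list (-1.07), zgc:77060 (-1.02) and, just past the limit, si:ch211-5k11.2.

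The remaining 33 lists with at least 5 members did not stand apart, with medians between -0.08 and 0.09. They include fast muscle (-0.04), heart muscle (-0.03), kidney (-0.04), ribosomal proteins (-0.04), nuclear-encoded oxidative phosphorylation (-0.01), neutrophils (0.02), epidermis (0.02), cartilage (0.04) and melanophores (0.06). Neurons and synapses, at -0.04 over 53 members, lay just inside the limit at the 1.04th percentile. The yolk protein list had 2 entering members and was not placed.

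In the authors' deposited table, 109 loci had a q under 0.05, of which 36 were higher and 73 lower in the mutant. Of the 88 with a symbol in the authors' deposited table, 62 were lower and 27 belonged to 1 of the lists here, 8 of them to the exocrine pancreas. Those q-values rest on 1 pool per genotype and do not measure variation between clutches or pools.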

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

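All tests in this part were chosen after the result was seen. Loci without a gene symbol take no part in the comparison of genes, and 4 of them with a mean of at least 1 FPKM were higher in the mutant with a q under 0.05 in the authors' deposited table. A locus of 102 bases on chromosome 9 (13392007 to 13392108) was listed at 0 in wild type and at 5315 FPKM in the mutant. A locus of 125 bases on chromosome 21 (11237898 to 11238022) was listed at 0 and 89.0 FPKM, and one of 873 bases on chromosome 5 (74706465 to 74707337) at 0 and 6.60 FPKM. The longest, 6941 bases on chromosome 14 (11629450 to 11636390), stood at 1.45 and 3.78 FPKM. It begins just past the end of irg1l (11625681 to 11629239), which was also higher, at 4.90 and 11.8 FPKM. Whether this locus belongs to the irg1l transcript was not tested. By the same limits 8 unnamed loci were lower in the mutant, with log2 differences from -2.80 to -0.91, and 1 of them was listed at 0 in the mutant.

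The loci on chromosomes 9 and 21 are very short. Noise of very short loci is a candidate explanation for large differences there: the log2 difference of unnamed loci of up to 200 bases had an SD of 1.19 against 0.28 for loci over 500 bases, a ratio of 4.22. It went both ways there, with 51 of 428 short loci at least 2-fold higher and 59 lower. The 102-base locus on chromosome 9 shares its mutant value of 5315 FPKM exactly with a locus of the same length on chromosome 17 (21259561 to 21259662), as equal small numbers of reads would give. Whether more ribosomal RNA was left in the mutant library stays open, since 5.8S RNA was higher while 5S RNA was not. Summed over its loci, 5S RNA was lower at -0.46 on the log2 scale (1622 and 1177 FPKM). AL935186.6, the clone-based symbol beside the 5.8S locus, was higher at 90.4 and 243 FPKM. What it encodes was not examined. The comparison of SDs covers unnamed loci only and was not run on the short RNA symbols. For some of these the locus length is not that of the RNA. The locus of dre-mir-10d (chromosome 6, 10692096 to 10813750) is long but shared with 5 other gene models. An effect of genotype was not tested.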

How the results depend on the processing

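Counts of genes past 2-fold moved by more than 1.5 times with the treatment of low values. With a pseudocount of 5, 22 genes were higher and 40 lower, against 54 and 82 as reported. With a pseudocount of 0.1, 134 were lower, and with a mean of at least 5, 33 were higher. A pseudocount shrinks or widens the differences of low genes by its construction, and a higher mean leaves fewer genes. Without short RNA symbols, an alternative chosen after seeing the data, 36 were higher and 78 lower. The median of all genes stayed between 0 and 0.009, and 18 to 20 lists lay below and 5 to 7 above the random lists. Gluconeogenesis lost its place without the filter, and the integrated stress response with a pseudocount of 5. Neurons and synapses passed the lower limit under 4 settings and heat shock the upper one with a pseudocount of 0.1. Of the named genes, SNORA57 reversed, to -0.18 by its highest locus; the cause was not tested. Rescaling to a median of 0 moved values by about 0.004, too little to test any result, and restriction to tested loci left the counts at 54 and 82. No paired analysis was possible because each genotype has 1 pool, and leaving out a replicate was not possible either. Unknown depth means that no counting error can be given for low genes and short loci.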

Other observations

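The tests in this part were chosen after the result was seen, except the early gene list and the question of single larvae. Beyond the genes that the rule named, loci with a q under 0.05 in the authors' deposited table include, on the lower side, the meprin mep1a.2 (13.3 and 5.06 FPKM), the disaccharidase symbol SI (27.4 and 11.9 FPKM), the tyrosine and tryptophan degrading enzymes tat (27.4 and 11.2 FPKM) and tdo2b (11.5 and 4.67 FPKM), and the muscle ubiquitin ligase fbxo32 (11.8 and 3.75 FPKM). On the higher side they include il11a (listed at 0 and 0.43 FPKM), irg1l (4.90 and 11.8 FPKM), the matrix metalloproteinase mmp11b (2.78 and 6.04 FPKM) and the adrenomedullin symbol ADM (2 of 2) (5.12 and 12.5 FPKM). These genes were picked after their values were seen.

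Genes of the pancreas and intestine were lower together. A few genes taking more of the mutant library would lower matched random lists as well, and the exocrine pancreas median of -1.12 lay far below their central 99%, from -0.12 to 0.11. A smaller share of exocrine pancreas cells in the mutant pool cannot be told apart from lower expression per cell, since both would give the 94.1% of measured members at or below -0.5. A general delay of the mutant larvae cannot be told apart from these either: early embryonic and progenitor genes, listed before their values were seen, had a median of 0.04 at percentile 89.8, within the random error of the limit of 90 that was set to argue against a delay. An effect of the lri12 genotype itself stays open, as 1 pool per genotype cannot separate it from a difference between pools.

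The hatching enzyme gene he1a had one of the highest differences. Reads moved to it from other gene models of its locus would lower those models, and only aox1 (2.82 and 2.69 FPKM) and he2 (0.040 and 0.014 FPKM) were lower, while aox3 stood at 2.82 and 3.29 FPKM. The gain of he1a was 307 times their summed loss in FPKM, so these models would have to be about that much longer than he1a in a locus of 63791 bases, which argues against this explanation. Whether 1 or a few larvae of the mutant pool carry the gland cannot be told apart from a higher level in all of them, because there is 1 pool per genotype. Other loci were gathered after their values were seen, because they were higher: he1b in the same locus (1.33 and 8.11 FPKM) and cathepsin L family copies on chromosome 12 between 17583551 and 18018797, among them BX465840.1 (0.59 and 6.39 FPKM) and zgc:174153 (0.22 and 2.71 FPKM). Within each family the genes are related copies and not separate evidence. The cathepsin L copies are not copies of he1a or he1b and lie on another chromosome. Because all were gathered for being higher, they do not count as support. Sharing of reads among the cathepsin copies was not tested.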
